A study of Mus musculus with 15 samples.

How the data were processed

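Gene expression was measured by sequencing of polyadenylated RNA in 15 mouse libraries, 9 from embryonic germ cells (EGC) and 6 from embryonic stem cells (ESC). Cells were grown on mouse embryonic fibroblast feeders, sorted for the surface antigen SSEA1 and taken at passage 6. Libraries were made with a TruSeq kit and sequenced as paired ends on a HiSeq instrument. Per the labels, Picard 1.100, STAR 2.3.0, SAMtools 0.1.18.0, HTSeq 0.6.0 and edgeR 3.8.6 were used with the GRCm38 (mm10) genome build. The labels do not state the role or the order of these tools, nor how the values were scaled.

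The deposited table gives values in TPM, a share of all transcripts scaled to the same sum, for 34372 genes in each library. Every column summed to 1000000. The table holds no read counts, so the depth of each library is unknown, no interval or detection floor was computed, and the spread between replicates is the only error given. Between 12498 and 13041 genes reached 1 TPM per library, and mitochondrial transcripts took 4.92% to 7.85% of the TPM. No symbol was repeated and no pair of libraries was identical. Positions on GRCm38 came from GENCODE release M21 for 30617 genes (89.1%), of which 28492 matched by symbol and 2125 by an older symbol.

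Karyotype and embryonic stage were taken from the header of the table, where a blank cell was read as belonging to the label at its left. This gave 6 header labels: E12.5 XY EGC (EGC 1 to 3), E11.5 XY EGC (EGC 4 to 6), E11.5 XX EGC (EGC 7 and 9), E11.5 XO EGC (EGC 8), XX ESC (ESC 1 to 3) and XY ESC (ESC 4 to 6). Karyotype was never inferred from expression. It is not stated whether libraries under 1 label come from separate lines or from clones of 1 line, so label, stage, karyotype and line cannot be separated. The XO label has 1 library, which counts among the 9 EGC libraries in the tests of EGC against ESC. In the comparisons by karyotype and stage it is given as values only.

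The comparison of EGC with ESC, its tests, the gene lists and the rule for named genes were fixed before the data were examined. The comparisons by karyotype and stage were chosen after the header had been read. Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1, using a moderated test with a mean-variance trend, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. For EGC against ESC, 12909 genes with at least 1 TPM in at least 6 libraries were tested without covariates. For the comparisons by label, a model with 1 mean per header label (9 residual degrees of freedom) was fitted to 13879 genes with at least 1 TPM in at least 2 libraries. Its errors measure only the spread between libraries under 1 label, which may be clones of 1 line. The contrast of EGC with ESC in XY cells weighted both EGC stages equally. Fold changes on this scale understate changes of genes near or under 1 TPM. Errors on log2 fold changes are standard errors (SE), and errors on TPM are standard deviations (SD). Python 3.11.15 was used for reading the table and for figures.

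A set of 25 gene lists with 495 members was fixed: general and naive pluripotency, formative and primed pluripotency, primordial germ cell identity, germline genes silenced by promoter DNA methylation, paternally and maternally expressed imprinted genes, DNA methylation machinery, ERK targets and feedback phosphatases, X-linked candidate dosage regulators, the X inactivation centre, Y-linked genes, the 2-cell-like state, WNT targets, TGF-beta targets, endoderm, mesoderm, neuroectoderm, trophoblast, fibroblast markers, mitochondrial transcripts, p53 and stress response, glycolysis, cholesterol synthesis, Polycomb regulators and HOX genes. Each list was tested against all other genes with camera (preset correlation 0.01, adjusted over lists). Camera with an estimated correlation and fry were run beside it.

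The rule for named genes took Dusp9, Xist and the Y-linked genes, and the 10 largest changes past the threshold in each direction, leaving out predicted genes (symbols of Gm with a number or ending in Rik), bare identifiers, Y-linked genes and Xist. Where fewer than 3 genes passed in a direction, the 3 with the smallest p were added as not past the threshold. Up to 4 members with the smallest p were taken from each list with a called member or a called test, and up to 2 with the highest mean from the others. The genes discussed were picked from those the rule named, after their values had been seen. Genes given outside the rule are said to be so. The result of 1 gene named by the rule is not reported here.

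The X-to-autosome score of a library is the median over expressed X-linked genes of log2(TPM + 1) minus the mean of all libraries, less the same median over autosomal genes, with Dusp9 left out. Other chromosomes were scored the same way. Scores, Dusp9 and the fibroblast marker mean were compared by 2-sided exact permutation tests. These used 5005 arrangements for EGC against ESC and 2002 for the 5 XX against the 9 XY libraries, for which the smallest possible p is 0.0004995. All exact permutation tests of groups take libraries as independent. Libraries under 1 label may come from 1 line, so these p may be too small. Principal components came from the 2000 most variable genes. Relations across libraries were computed within the 9 XY libraries over all 362880 pairings, 5 relations in the family. They were not computed over all libraries, because X scores fall into separate clusters by karyotype.

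The tests were checked on simulated data with the observed gene means and spreads. A change of 1 log2 unit was recovered for 84% of 50 genes in EGC against ESC with 3.53% false calls, and for 90% to 98% in the comparisons by label with up to 6.95% false calls. The simulated libraries were drawn independently, without differences between labels or correlation within them. These rates therefore hold for independent libraries and may not hold for the real ones. Alternatives covered the pseudocount, the filter, scaling by quantiles or median ratios, the variance model, array weights, covariates, rank tests, treatment of the header labels as correlated, left-out genes and each library left out in turn. Header labels were treated as correlated only for EGC against ESC. No paired analysis was possible because the labels give no link between an EGC and an ESC library.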

Results

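Transcript levels were measured in 15 mouse libraries. The 9 EGC libraries come from pluripotent lines derived from primordial germ cells of E11.5 or E12.5 embryos, and the 6 ESC libraries from embryonic stem cells. The header gave 3 E12.5 XY EGC, 3 E11.5 XY EGC, 2 E11.5 XX EGC, 1 E11.5 XO EGC, 3 XX ESC and 3 XY ESC libraries. Values are TPM, which sum to 1000000 in every library, and the read depth behind them is unknown. The title of the series names DUSP9 as a dose-dependent, X-linked factor, so Dusp9, the number of X chromosomes and the EGC or ESC origin frame the comparisons.

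Dusp9, a phosphatase that acts on ERK kinases (chromosome X, 73639419 to 73643514), was higher in XX than in XY libraries of both cell types. It also differed between the XY EGC stages. Its level was 163.3 ± 3.89 TPM in XX ESC (SD, n = 3) and 71.7 ± 4.68 TPM in XY ESC (n = 3). It was 137.8 ± 5.94 TPM in XX EGC (n = 2) and 33.1 ± 2.54 TPM in E11.5 XY EGC (n = 3), while E12.5 XY EGC had 78.2 ± 8.90 TPM (n = 3). The XO library had 33.6 TPM, within the range of the E11.5 XY libraries (30.7 to 35.8 TPM). Across the 5 XX and 9 XY libraries, Dusp9 was 1.41 log2 units higher in XX (exact permutation p = 0.0004995, the smallest possible), and every XX library exceeded every XY library. This p takes libraries under 1 label as independent, which the labels do not state. The X-linked genes as a whole moved the same way. The X-to-autosome score was 0.601 ± 0.0494 in XX (SD, n = 5) and -0.294 ± 0.0475 in XY libraries (n = 9), a difference of 0.895 or 1.86-fold (exact permutation p = 0.0004995). The XO library scored -0.362. Xist, the RNA that coats an inactive X chromosome, was low in every label, at 1.15 ± 0.561 TPM in XX ESC and 1.16 ± 0.692 TPM in XX EGC against 0.115 TPM or less on average in the XY labels.

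**Figure D1:**
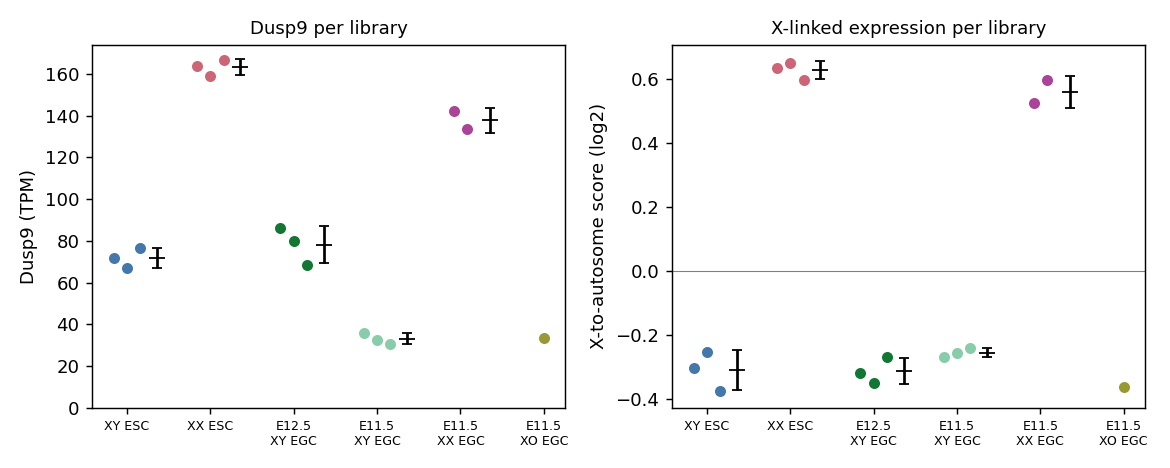
Dusp9 in TPM and the X-to-autosome score (log2) of each library by header label, with each point a library and bars for mean and SD. XX libraries lie at 133.6 to 166.8 TPM of Dusp9 and XY libraries at 30.7 to 86.2 TPM.

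EGC and ESC were compared first as wholes, which asks whether the origin of the line leaves a transcriptional difference. Mest, which is expressed from the paternal copy (chromosome 6, 30723547 to 30748465), was higher in EGC at 44.0 ± 5.62 TPM (SD, n = 9) than in ESC at 23.9 ± 1.76 TPM (n = 6). Snrpn, another paternally expressed gene (chromosome 7, 59982495 to 60140219), had 149 ± 10.01 TPM in EGC and 86.4 ± 14.2 TPM in ESC. For both genes the lowest EGC library (36.98 and 132.0 TPM) exceeded the highest ESC library (26.5 and 102.1 TPM). Cdkn1c, a maternally expressed inhibitor of cell division (chromosome 7, 143458339 to 143461050), was lower in EGC, with 2.72 ± 0.861 TPM against 7.81 ± 1.87 TPM, again with no overlap between the groups. Bgn, a matrix proteoglycan abundant in fibroblasts, was higher in EGC (8.43 ± 2.05 against 3.84 ± 0.754 TPM), together with the fibroblast markers described below.

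By limma, 6 of 12909 genes passed the threshold, 3 higher and 3 lower in EGC, while 1164 had an unadjusted p under 0.05. The log2 fold changes were 0.85 ± 0.08 (SE) for Mest (adjusted p = 0.000266), 0.79 ± 0.09 for Snrpn (adjusted p = 0.000532), 0.95 ± 0.15 for Bgn (adjusted p = 0.0253), -1.25 ± 0.18 for Cdkn1c (adjusted p = 0.0111) and -0.52 ± 0.09 for Vps13d (adjusted p = 0.0367). The last was the predicted gene Gm6158 at -3.83 ± 0.64, outside the rule for named genes and given after its value was seen. With karyotype as a factor 21 genes passed, among them Meg3 (adjusted p = 4.793e-06) and Sgce (0.0486). Without that factor Meg3, a maternally expressed non-coding RNA, had 501 ± 198 TPM in EGC and 124 ± 81.7 TPM in ESC but did not pass (2.17 ± 0.42, adjusted p = 0.0875), nor did the cell-division gene Cenpf (-0.84 ± 0.16, adjusted p = 0.0875) or the paternally expressed Sgce (0.89 ± 0.18, adjusted p = 0.0894). Dusp9 averaged 71.4 ± 43.3 TPM in EGC and 117.5 ± 50.3 TPM in ESC. Its difference of -0.82 was not past the threshold (limma adjusted p = 0.549, exact permutation p = 0.0619). XX libraries made up 2 of 9 EGC and 3 of 6 ESC, and the X-to-autosome score differed by -0.264 (exact permutation p = 0.234).

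**Figure D2:**
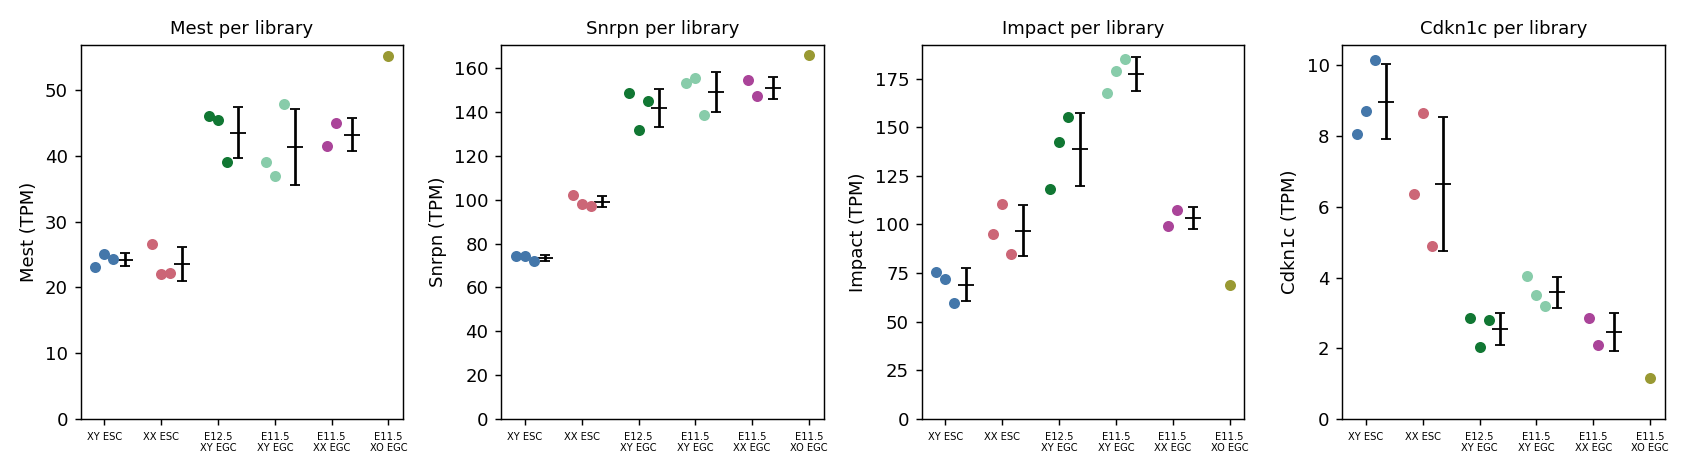
Mest, Snrpn, Impact and Cdkn1c in TPM in each library by header label, with each point a library and bars for mean and SD. Mest and Snrpn lie higher in all 9 EGC libraries than in all 6 ESC libraries.

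Of the 25 lists, 6 were called by camera in this comparison. Paternally expressed imprinted genes were higher in EGC (median log2 fold change 0.32, adjusted p = 0.000334, and adjusted p = 0.56 with an estimated correlation). Of 21 measured members 2 rose, Mest and Snrpn, 19 did not pass, and 5 were higher when adjusted over the list alone. Fibroblast markers were higher in EGC (median 0.61, adjusted p = 1.97e-06, and adjusted p = 0.0558 with an estimated correlation), with 1 of 16 past the threshold and 6 when adjusted over the list alone. The collagen genes Col1a1 and Col1a2 had 5.61 ± 2.98 and 5.54 ± 3.04 TPM in EGC against 1.77 ± 0.651 and 1.61 ± 0.992 TPM in ESC without passing (log2 fold changes 1.18 and 1.29, adjusted p = 0.0894 for each). The mean of the fibroblast markers was 2.74 ± 0.337 in EGC and 2.18 ± 0.151 in ESC (exact permutation p = 0.0005994). Mitochondrial transcripts were higher in EGC for 14 of 15 members (median 0.30, adjusted p = 6.71e-06, and adjusted p = 0.56 with an estimated correlation), none past the threshold by limma and 5 when adjusted over the list alone. ERK targets were higher (median 0.15, 22 of 28 members positive, adjusted p = 0.00698, and adjusted p = 0.805 with an estimated correlation), with 1 member past the threshold when adjusted over the list alone. The mean standardized level of ERK targets without Dusp9 was 0.0257 to 0.977 in the XY EGC libraries. It was -0.509 and -0.683 in XX EGC, -0.447 in the XO library and -0.755 to -0.0231 in ESC. The rise therefore lay in XY EGC. X-linked dosage regulators were lower for all 20 members (median -0.23, adjusted p = 0.000447), as were germline genes silenced by promoter methylation for 19 of 26 (median -0.33, adjusted p = 0.00942). Both had an adjusted p = 0.805 with an estimated correlation and no member past the threshold, over all genes or adjusted over the list alone. The share of XX libraries was lower in EGC than in ESC, and within XY cells camera did not call the X-linked list.

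The other 19 lists had adjusted p between 0.143 (p53 and stress response) and 0.968. They cover general and formative pluripotency, germ cell identity, maternally expressed imprinted genes, DNA methylation machinery, the X inactivation centre, Y-linked genes, the 2-cell-like state, WNT and TGF-beta targets, the endoderm, mesoderm, neuroectoderm and trophoblast lists, glycolysis, cholesterol synthesis, Polycomb regulators and HOX genes. Adjusted over the list alone, 1 member was higher and 2 lower among maternally expressed imprinted genes, 1 was higher in the DNA methylation list and 1 in the trophoblast list, and none passed in the rest. The germline list was no longer called without EGC 2 (adjusted p = 0.0826), ESC 2 (0.0833) or ESC 3 (0.0704), and the ERK list was not without ESC 2 (0.0564). With the fibroblast marker mean as a covariate the germline (0.0869), ERK (0.383), X-linked dosage (0.226) and fibroblast lists (0.226) were not called.

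The number of called genes was 21 without EGC 3, 3 without any of EGC 5, EGC 7, EGC 9, ESC 3 or ESC 4, and 2 without ESC 5 or ESC 6. Mest and Snrpn passed with each library left out. Cdkn1c did not pass without ESC 5 (adjusted p = 0.0553) or ESC 6 (0.0529), and Bgn did not without EGC 5 (0.0643), EGC 7 (0.0511), EGC 9 (0.0512), ESC 3 (0.0949), ESC 4 (0.0908), ESC 5 (0.0760) or ESC 6 (0.0864). Vps13d passed only with EGC 3 or EGC 8 as the library left out, and Gm6158 only with EGC 3 or EGC 4, with adjusted p of up to 0.125 otherwise (without ESC 3). Without EGC 3, Cenpf (adjusted p = 0.0342), Col1a1 (0.0391) and Col1a2 (0.0419) passed, as did Cenpf without EGC 1 (0.0331) and with median-ratio (0.0314) or quantile scaling (0.0423). When libraries under 1 header label were treated as correlated (consensus correlation 0.751), limma called no gene, with 133 at an unadjusted p under 0.05. This correlation also takes up karyotype and stage differences between labels. The log2 fold changes did not shrink, at 0.89 ± 0.19 for Mest (adjusted p = 0.855) and 0.82 ± 0.13 for Snrpn (adjusted p = 0.0941), but their SE grew. The share of called genes that were higher was 50% here, 37.5% with median-ratio scaling and 44.4% with quantile scaling.

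XX and XY cells were compared within ESC, which asks what a second active X chromosome goes with. Germline genes silenced by promoter methylation were higher in XX ESC, with 20 of 28 measured members rising, 2 falling and 6 not past the threshold (median log2 fold change 1.14). Asz1, a gene of the germline piRNA pathway, had 10.7 ± 1.21 TPM in XX ESC (SD, n = 3) and 0.424 ± 0.165 TPM in XY ESC (n = 3). Sycp1, a meiotic chromosome protein, had 48.1 ± 6.29 against 7.97 ± 1.23 TPM, and Tuba3a, a testis tubulin, 151 ± 19.2 against 30.6 ± 2.57 TPM. Naive pluripotency genes were also higher, with 17 of 25 rising and 3 falling. Camera with an estimated correlation called neither the germline nor the naive list. Nanog had 924 ± 22.0 against 453 ± 26.1 TPM, and Tcl1, Tbx3 and Prdm14 rose by 1.18, 1.21 and 0.94 log2 units, while Lin28a fell by 0.92.

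Among X-linked genes, 510 of 588 were higher and 10 lower in XX ESC, with a median log2 fold change of 0.97 against 0.03 for autosomal genes. All 20 X-linked dosage regulators rose. Dusp9 rose by 1.18 ± 0.08 (SE, adjusted p = 2.126e-07), the histone demethylase gene Kdm5c by 1.14, Klhl13 by 1.87 and Zfp185 by 1.54. All 5 measured genes of the X inactivation centre rose, with Xist at 0.97 ± 0.19. Several X-linked genes rose far beyond 2-fold. Scml2, a Polycomb-related gene of the male germline, had 89.1 ± 12.4 TPM in XX against 2.11 ± 0.219 TPM in XY, and Xlr, Usp26, Rhox2a and Rhox1 rose by 4.39, 4.36, 4.23 and 3.91 log2 units. The largest autosomal rise among the named genes was Ube2l6, an ISG15-conjugating enzyme, at 30.3 ± 5.73 against 0.760 ± 0.253 TPM. The 3 measured Y-linked genes Eif2s3y, Ddx3y and Uty were lower in XX by -6.78, -4.67 and -4.09 log2 units.

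Imprinted genes moved both ways. Of 23 paternally expressed genes 14 rose and 3 fell in XX ESC. Ndn and Peg12 rose by 1.62 and 1.70 and Zrsr1 by 0.88 log2 units, while Nnat fell by 1.80. Among maternally expressed genes, Phlda2, a regulator of placental growth, had 10.8 ± 1.58 TPM in XX and 81.6 ± 10.6 TPM in XY ESC. Meg3 fell by 1.95 and the imprinted transporter gene Slc22a18 by 1.16. Of the DNA methylation genes, the de novo methyltransferase gene Dnmt3a fell by 0.66 ± 0.09 and its cofactor Dnmt3l rose by 1.05 ± 0.13. Among ERK targets 6 rose and 10 fell of 30. Egr1, a fast ERK response gene, had 5.12 ± 0.489 against 22.6 ± 5.13 TPM and Dusp5 fell by 0.66, while Dusp16 rose by 0.54. Cholesterol genes on the X chromosome rose (Ebp by 1.12 and Nsdhl by 0.88) and the autosomal Lss fell by 0.73. The formative transcription factor genes Otx2 and Foxd3 rose by 1.96 and 1.92. Rgs11 and the myosin light chain gene Myl3 fell by 2.35 and 3.36.

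In all, 3786 genes were higher and 2681 lower of 13879 tested, and 752 and 259 of these changed at least 2-fold. The higher share was 58.5%, against 53.3% with median-ratio and 45.5% with quantile scaling. Camera called 5 lists: X-linked dosage regulators (adjusted p = 1.06e-10), Y-linked genes (2.84e-06), germline genes (4.12e-05), naive pluripotency (0.00369) and the X inactivation centre (0.00875). With an estimated correlation the adjusted p was 0.119, 0.119, 0.558, 0.558 and 0.558. Adjusted over the list alone, 20 germline genes rose and 3 fell, and 17 naive pluripotency genes rose and 4 fell. Without ESC 3, whose chromosome 13 genes were high, 9 lists were called, and calls on chromosome 13 changed from 178 higher and 21 lower of 500 to 140 higher and 50 lower.

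The same comparison was made in E11.5 EGC. Fos had 24.3 ± 7.06 TPM in XX EGC (SD, n = 2) and 626.5 ± 75.7 TPM in E11.5 XY EGC (n = 3). Egr1 had 2.94 ± 0.0567 against 142 ± 19.3 TPM, and Fosb, Egr2, Atf3 and Klf6 fell by 5.66, 3.11, 2.94 and 1.91 log2 units. Of 30 measured ERK targets 18 fell and 5 rose (median -0.53), among them Dusp6, a feedback phosphatase of ERK, at 15.1 ± 0.785 against 43.3 ± 4.36 TPM. The Notch ligand gene Dll1, the lysophospholipase gene Enpp2 and the purine enzyme gene Adssl1 fell by 4.17, 3.51 and 2.73. Of 19 p53 and stress genes 10 fell and 5 rose, with Cdkn1a, Mdm2 and Trp53inp1 lower by -0.84, -0.84 and -1.40.

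X-linked genes were higher in XX EGC, 463 of 588 rising and 14 falling. Dusp9 rose by 2.03 ± 0.09 (SE, adjusted p = 1.056e-08), Klhl13 by 2.02, Zfp185 by 1.41 and Eras, an X-linked RAS gene of embryonic stem cells, by 1.38. Rhox1, Nxf7 and Rhox2a rose by 4.55, 4.22 and 3.91. The autosomal Pramel7 was listed at 0 in all 3 E11.5 XY libraries and had 14.5 ± 0.309 TPM in XX. Xist rose by 0.92 ± 0.21 (adjusted p = 0.00279), a call lost without EGC 9 (adjusted p = 0.0618). Eif2s3y, Ddx3y and Uty were lower by -6.38, -4.73 and -4.03. Nanog, Prdm14, Tcl1 and Dppa2 rose by 0.76, 1.01, 0.87 and 1.52, within a list of which 11 of 25 rose and 6 fell. Dnmt3l rose by 1.13, and Tuba3a had 94.2 ± 3.74 against 20.2 ± 4.94 TPM. Of the imprinted genes, Ndn and Peg12 rose by 1.45 and 2.04, and Meg3, Slc22a18 and Phlda2 fell by 1.76, 1.39 and 1.29.

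Of 13879 genes 3638 were higher and 3251 lower, 680 and 376 of them at least 2-fold. Camera called X-linked dosage regulators higher (18 of 20 members, adjusted p = 8.89e-08), and called Y-linked genes (1.75e-05) and ERK targets (0.000392) lower. With an estimated correlation the adjusted p was 0.177, 0.177 and 0.868. The list-alone adjustment gave 5 rising and 19 falling ERK targets. Against E12.5 XY EGC as the reference, 2740 genes were higher and 4136 lower, the difference in Dusp9 was 0.81, and 3 ERK targets were higher and 17 lower (adjusted p = 0.0162, and adjusted p = 0.789 with an estimated correlation). Camera also called germline genes higher with this reference (14 higher and 5 lower, adjusted p = 0.00377), as well as naive pluripotency (15 and 7, adjusted p = 0.0162) and the X inactivation centre (4 and 0, adjusted p = 0.0331), lists not called against E11.5 XY EGC. With an estimated correlation the adjusted p of these lists was 0.726, 0.726 and 0.712. X-linked dosage regulators (adjusted p = 3.47e-08) and Y-linked genes (7.22e-05) kept their calls, each with an adjusted p = 0.23 with an estimated correlation. Phlda2 (adjusted p = 0.169) and Atf3 (adjusted p = 0.453) did not pass against that reference.

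The XX and XY differences in ESC and EGC overlapped widely. Of 12959 autosomal genes, 1789 were higher in XX in both cell types (769.2 would be by independence), 1658 were lower in both (643.8 by independence) and 167 went opposite ways (1416 by independence). The log2 fold changes correlated across genes with r = 0.663, and genes are not independent replicates. The difference between both effects was tested directly. It passed for 2164 genes, 844 with a more positive XX effect in EGC and 1320 with a more negative one. With E11.5 XY EGC as the reference, the Dusp9 effect was larger in EGC by 0.85 ± 0.13 (SE, adjusted p = 0.002). With E12.5 XY EGC it was smaller in EGC, by -0.36 ± 0.13, and not past the threshold (adjusted p = 0.0649), so the direction depends on the reference. Fosb, Fos and Egr1 had effects lower in EGC by -5.03 ± 0.28, -3.95 ± 0.23 and -3.25 ± 0.22, and Dusp6 by -0.94 ± 0.17. Against E12.5 XY EGC these were -1.11 ± 0.28, -1.54 ± 0.23, -1.87 ± 0.22 and -0.24 ± 0.17, and Dusp6 did not pass (adjusted p = 0.360). The imprinted genes Impact, Sgce and Zrsr1 differed by -1.25 ± 0.17, -1.26 ± 0.21 and -0.89 ± 0.13, and Phlda2 by 1.52 ± 0.17. Against E12.5 XY EGC they differed by -0.895, -0.997, -0.726 and 2.59. Snrpn differed by -0.41 ± 0.09, a call lost without EGC 9 (adjusted p = 0.0564).

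Camera called 4 lists for this difference: germline genes lower (0 of 28 with a more positive and 11 with a more negative effect, among them Brdt at -1.13, adjusted p = 0.00442), ERK targets lower (1 and 9 of 30, adjusted p = 0.00442), cholesterol synthesis higher (4 and 0 of 20, among them Lss at 0.69, adjusted p = 0.00491) and p53 and stress genes lower (0 and 6 of 19, among them Cdkn1a at -0.63, adjusted p = 0.0463). Each had an adjusted p = 0.896 with an estimated correlation. With E12.5 XY EGC as the reference the ERK list kept its call (adjusted p = 0.0257, and adjusted p = 0.701 with an estimated correlation), while the germline (0.0729), cholesterol (0.0729) and p53 lists (0.592) and Lss (0.449) did not. Camera then also called paternally expressed imprinted genes (adjusted p = 0.000267) and trophoblast genes (0.0374) lower, and fibroblast markers (0.000634) and mitochondrial transcripts (0.0374) higher, each with an adjusted p = 0.701 with an estimated correlation. With the E11.5 reference and adjusted over the list alone, the counts for germline, ERK, cholesterol and p53 genes were 0 and 11, 1 and 11, 8 and 0, and 0 and 7. The p53 list was not called without EGC 4 (adjusted p = 0.102), EGC 9 (0.0828), ESC 3 (0.149) or ESC 5 (0.113), nor the ERK list without ESC 3 (0.0664). With the fibroblast marker mean as a covariate the p53 list was not called either (0.0519). The gene count was 1244 without EGC 5, 698 without EGC 7, 1134 without EGC 9, 1347 without ESC 1, 1402 without ESC 2 and 1238 without ESC 6. The share with a more positive effect was 39%, against 46.7% with median-ratio and 49.7% with quantile scaling.

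Within XY cells, EGC of both stages were compared with ESC, which removes the unequal share of XX libraries. Paternally expressed imprinted genes were higher in XY EGC, with 12 of 23 rising and none falling (median log2 fold change 0.44). Camera with an estimated correlation did not call this list. Snrpn had 146 ± 9.01 TPM in XY EGC (SD, n = 6) and 73.5 ± 1.26 TPM in XY ESC (n = 3), Impact 158 ± 24.9 against 69.1 ± 8.31 TPM, Sgce 32.2 ± 4.76 against 11.7 ± 0.901 TPM and Zrsr1 11.3 ± 0.794 against 5.499 ± 0.677 TPM. Maternally expressed genes went both ways, 2 of 16 rising and 4 falling. Phlda2 had 22.4 ± 9.19 against 81.6 ± 10.6 TPM, Cdkn1c 3.07 ± 0.689 against 8.98 ± 1.06 TPM, Slc22a18 fell by 0.83 and Grb10, a growth factor adaptor gene, by 3.16, and Meg3 rose by 1.51. In EGC 6, Grb10 had 97.3 TPM, against 4.06 to 8.36 TPM in the other 5 XY EGC libraries, values given after they were seen. Dusp9 was lower by -0.49 ± 0.07 (SE, adjusted p = 0.00249) as the mean of both EGC stages. This came from E11.5, at -1.09 ± 0.08 (adjusted p = 3.326e-06), while E12.5 was at 0.12 ± 0.08 (adjusted p = 0.439).

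Of 30 ERK targets 12 rose and 1 fell, with Egr1, Fos and Fosb higher by 1.93, 1.85 and 3.01 and Dusp6 by 0.62. The transcription factor genes Klf6 and Klf4 rose by 1.03 and 0.97. These are means of unlike stages. At E11.5, Egr1, Fos, Fosb and Dusp6 were higher than in XY ESC by 2.61, 3.05, 4.98 and 0.98, and at E12.5 by 1.24, 0.65, 1.05 and 0.27. Of the p53 and stress genes 6 of 19 rose and none fell, among them Cdkn1a at 0.42, Sesn2 at 0.46 and Mdm2 at 0.54. The fibroblast markers were higher in the same libraries, with 3 of 18 rising, among them Lox at 1.01, and so were 6 of 15 mitochondrial transcripts, among them mt-Nd1 at 0.61. At E12.5 alone, Dusp6 (adjusted p = 0.182), Klf6 (0.123), Klf4 (0.209), Mdm2 (0.188), Lox (0.793) and mt-Nd1 (0.384) did not pass against XY ESC. Camera called paternally expressed imprinted genes (adjusted p = 1.92e-08), ERK targets (2.21e-06), mitochondrial transcripts (0.000309), fibroblast markers (0.000441) and p53 and stress genes (0.000675) higher, and glycolysis lower (3 of 21 falling and 1 rising, adjusted p = 0.00444). In the same order, the adjusted p was 0.135, 0.616, 0.765, 0.66, 0.158 and 0.688 with an estimated correlation. Adjusted over the list alone, 12, 15, 7, 10 and 7 members rose, and of glycolysis 5 fell and 1 rose. The glycolysis call was lost without EGC 1 (adjusted p = 0.0582) or ESC 6 (0.0553).

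The fit with 1 mean per label called 651 genes higher and 204 lower of 13879. In the 9 XY libraries alone, a fit with 1 mean per label called 795 genes, and a fit with only EGC and ESC as groups, in which the difference between both EGC stages counts as spread, called 8. The count was 488 without EGC 5, 293 without ESC 4, 450 without ESC 5, 252 without ESC 6 and 294 with the fibroblast marker mean as a covariate, with which Mdm2 (adjusted p = 0.0657), Sesn2 (0.0536) and Grb10 (0.0681) did not pass. Mdm2 also did not without ESC 6 (0.0831). The share of higher genes was 76.1%, against 58.9% with median-ratio and 56.2% with quantile scaling.

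Within XX cells, 2 EGC and 3 ESC libraries were compared. Mest had 43.2 ± 2.52 TPM in XX EGC (SD, n = 2) and 23.6 ± 2.55 TPM in XX ESC (n = 3), Snrpn 151 ± 4.96 against 99.2 ± 2.55 TPM and Meg3 196 ± 2.40 against 50.4 ± 3.67 TPM. Cdkn1c and Slc22a18 fell by 1.12 and 0.84, and the growth factor receptor gene Igf2r by 0.80. Of 23 paternally expressed genes 3 rose and none fell, and the list was not called. Of 18 fibroblast markers 7 rose and 1 fell (median 0.84, adjusted p = 1.37e-06, and adjusted p = 0.799 with an estimated correlation), among them Lox at 5.14 ± 0.270 against 0.822 ± 0.123 TPM and S100a4 at 5.09 ± 0.0301 against 1.36 ± 0.249 TPM, while Fn1 fell by 0.88. Germline genes were lower, with 6 of 28 falling and none rising (adjusted p = 0.00631, and adjusted p = 0.799 with an estimated correlation), among them Tuba3b by -1.26 and the bromodomain gene Brdt by -0.90. Aqp3, a water and glycerol channel gene, and Ube2l6 fell by 1.37 and 1.60. Dusp9 differed by -0.24 ± 0.09 (SE, adjusted p = 0.104), not past the threshold. Mitochondrial transcripts were called higher (2 of 15 rising, adjusted p = 0.00631, and adjusted p = 0.799 with an estimated correlation), a call lost without EGC 9 (adjusted p = 0.714) and with quantile scaling (0.242).

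Adjusted over the list alone, 10 fibroblast markers rose and 1 fell, 7 germline genes fell and 4 mitochondrial transcripts rose. Of all 13879 genes 1740 passed, 1172 of them lower. The count was 366 without EGC 7, 353 without EGC 9, 856 without ESC 1, 1049 without ESC 2, 613 when only the 5 libraries compared were fitted and 81 with the fibroblast marker mean as a covariate, with which Tuba3b (adjusted p = 0.0785) and Brdt (0.103) did not pass. Cdkn1c was not called without EGC 9 (adjusted p = 0.0528). The share of higher genes was 32.6%, against 44.9% with median-ratio and 48% with quantile scaling. Without ESC 3, calls on chromosome 13 changed from 5 higher and 81 lower of 500 to 25 and 51.

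E12.5 and E11.5 XY EGC were compared for the embryonic stage of origin, the difference that the labels give between these libraries. Fos had 117.5 ± 13.5 TPM at E12.5 (SD, n = 3) and 626.5 ± 75.7 TPM at E11.5 (n = 3), Fosb 5.87 ± 1.11 against 103 ± 9.84 TPM and Egr1 54.4 ± 8.19 against 142 ± 19.3 TPM, and Egr2, Klf6, Klf4 and Klf2 fell by 2.40, 1.52, 1.28 and 0.80. The ERK list as a whole was not called (3 of 30 rising and 8 falling, adjusted p = 0.0974), but it was called lower without EGC 1 (0.0315) or EGC 2 (0.0429). Dusp9 was higher at E12.5 by 1.21 ± 0.08 (SE, adjusted p = 1.677e-06), with the X-linked genes Eras, Klhl13 and Tfe3 higher by 0.91, 0.96 and 0.72 and Rhox6, Rhox9 and Rhox5 by 2.51, 2.06 and 1.89. The DNA methyltransferase genes Dnmt3a, Dnmt3b and Dnmt1 rose by 0.96, 1.01 and 0.52. Both genes of the H19 and Igf2 imprinted pair rose, H19 to 395.5 ± 31.4 from 30.9 ± 5.99 TPM and Igf2 to 28.3 ± 8.80 from 3.19 ± 1.32 TPM.

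Of 23 paternally expressed imprinted genes 12 rose and 1 fell at E12.5, with Nnat and Sfmbt2 higher by 1.79 and 1.62, while the maternally expressed Phlda2 fell by 1.07. The keratin genes Krt8 and Krt18 rose by 2.17 and 1.39 and the homeobox gene Cdx1 by 1.91. Mitochondrial transcripts were lower, with 10 of 15 falling and none rising (adjusted p = 1.46e-05, and adjusted p = 0.559 with an estimated correlation), among them mt-Nd1 at 2226 ± 132.5 against 4096 ± 456.2 TPM and mt-Nd3 by -1.09. Of 18 fibroblast markers 8 fell and 2 rose (adjusted p = 0.0256), with Lox and S100a4 lower by -1.89 and -1.41, and of the p53 and stress genes 4 of 19 fell (adjusted p = 0.0491, and 2 when adjusted over the list alone). Each of these 3 lists had an adjusted p = 0.559 with an estimated correlation. The list-alone adjustment gave 10 falling mitochondrial transcripts, and 8 falling and 2 rising fibroblast markers.

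Of 13879 genes 3648 were higher and 1578 lower at E12.5. The higher share was 69.8%, against 50.6% with median-ratio and 49.6% with quantile scaling. The mitochondrial list kept its call with each library left out and with median-ratio scaling, but not with quantile scaling (adjusted p = 0.084). The fibroblast and p53 lists were not called with quantile scaling (0.107 and 0.108), median-ratio scaling (0.0908 and 0.0711) or the fibroblast covariate (0.168 and 0.0848). The fibroblast list was not called without EGC 3 (adjusted p = 0.0554) or EGC 4 (0.137), nor the p53 list without EGC 3 (0.0554), EGC 4 (0.083), EGC 5 (0.086), EGC 7 (0.0523), EGC 9 (0.0523), ESC 2 (0.0538) or ESC 3 (0.0509). The number of called lists was 7 without EGC 1, 5 without EGC 2 or EGC 6, and 1 without EGC 3 or EGC 4.

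The expression of whole chromosomes was even across most libraries. Chromosome X differed between XX and XY libraries by 0.895 log2 units, the widest difference of the 20 chromosomes scored. Smaller XX and XY differences passed for chromosomes 2, 4, 5, 6, 9, 10, 13, 15, 16, 17 and 19, the widest of these being 0.157 for chromosome 13 (exact permutation adjusted p = 0.0171) with ESC 3 among the XX libraries. No chromosome differed between EGC and ESC (smallest exact permutation adjusted p = 0.608, and chromosome 16 alone had an unadjusted p under 0.05, at 0.0348). In EGC 8, the XO library, 428 genes of chromosome 12 had a median of 0.416 log2 units, and in ESC 3, 459 genes of chromosome 13 had a median of 0.488.

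**Figure D3:**
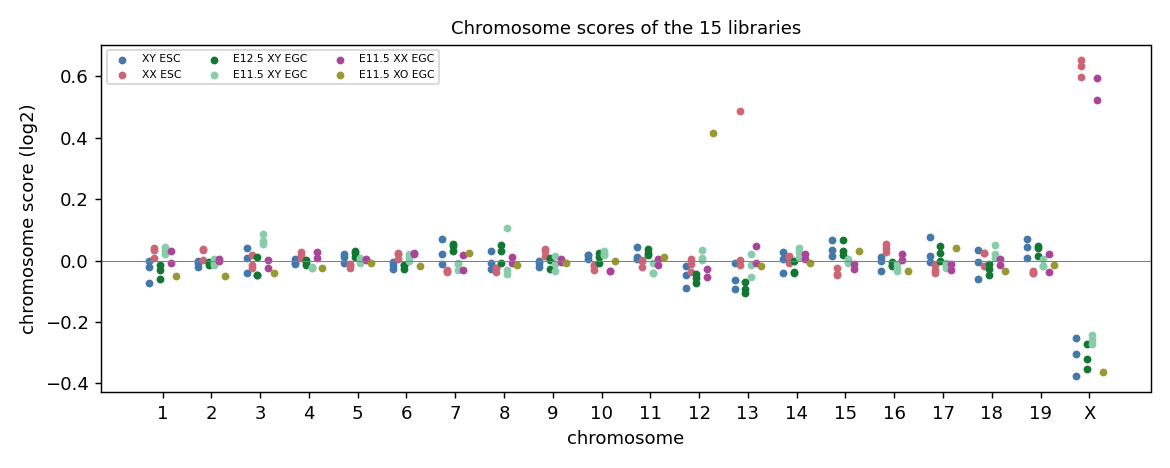
Score (log2) of each chromosome relative to the autosomes, with each point a library, coloured by header label. Chromosome X separates the XX libraries from the rest, and chromosome 12 in EGC 8 and chromosome 13 in ESC 3 stand at 0.416 and 0.488.

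Karyotype separated the libraries more than cell type did. The first principal component of the 2000 most variable genes held 50.4% of the variance and differed between XX and XY libraries (exact permutation p = 0.0004995, adjusted p = 0.001998 over 4 components) but not between EGC and ESC (p = 0.320). The second held 15.8% (exact permutation p = 0.0645 for EGC against ESC). Correlations between libraries of the same cell type were no higher than between cell types (Spearman difference -1e-04, 1-sided exact permutation p = 0.377). The median Spearman correlation was 0.990 within a label, 0.987 between E12.5 XY EGC and XY ESC, and 0.972 between E12.5 and E11.5 XY EGC.

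**Figure D4:**
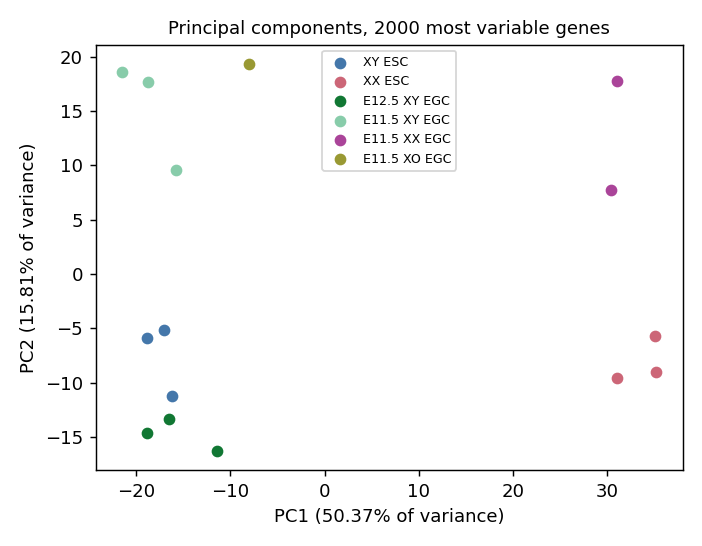
Principal components 1 and 2 of the 2000 most variable genes, with each point a library, coloured by header label. Component 1 (50.4% of the variance) separates XX from XY libraries.

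Among the 9 XY libraries, Dusp9 was lower where the X-to-autosome score, computed without Dusp9, was higher (Pearson r = -0.695, permutation p = 0.0339, adjusted p = 0.169, and Spearman rho = -0.85, permutation p = 0.00607, adjusted p = 0.0304, over 5 relations). Without the 2 libraries farthest from the median score, r was -0.715 (permutation p = 0.079) and rho -0.821 (permutation p = 0.0341, adjusted p = 0.17). The 3 E11.5 XY EGC libraries had lower Dusp9 than all 6 others, so the relation cannot be read apart from label. The other 4 relations, with germline, ERK, DNA methylation and naive pluripotency genes, had r of 0.523, 0.132, -0.305 and -0.079 and adjusted p of at least 0.375 (permutation). Without the 2 farthest libraries the first 2 turned to -0.351 and -0.003.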

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

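The tests on immediate-early genes were chosen only after the result was seen. Those on other splits of the libraries were set before. Those on chromosomes 12 and 13 were set before they were run, but for chromosomes and libraries already picked as raised.

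The score of chromosome 12 in EGC 8 was 0.416 log2 units (1.33-fold), far from the other 8 EGC libraries, and that of chromosome 13 in ESC 3 was 0.488 (1.40-fold), far from the other 5 ESC libraries. Levels were taken relative to the mean of all libraries. Of the genes on these chromosomes, 89% of 428 and 92.4% of 459 lay above the library's median over the other autosomes. After correction for GC content and gene length both medians remained (the smaller was 0.421), which argues against such a bias. Each of 4 parts of each chromosome, by gene position, was raised (lowest median 0.355), which argues against a few genes or 1 segment. A candidate explanation is an extra copy of the chromosome in the cells sequenced. The medians of these parts were 0.355 to 0.450 in EGC 8 and 0.468 to 0.5001 in ESC 3. They lay within the range taken to go with an extra copy, but below the proportional rise that such a copy in every cell would give. The range of medians taken to go with it was set for chromosomes already picked as raised, and no DNA was measured.

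Immediate-early genes were high in E11.5 XY EGC. The 11 measured members of this class, which was put together after their values were seen, had a median of 1.98 log2 units above XY ESC with 11 of 11 above 0. A response to dissociation or sorting could raise such genes, and the 5 heat shock genes tested as a sign of it had a median of 0.0347 (SD 0.277) with members on both sides, which leaves this open. Low Dusp9 alone may also be considered, since Dusp9 was lowest in these libraries. The XO library, with as little Dusp9, had an immediate-early median of -1.23 (0 of 11 above 0), and E12.5 XY EGC, with Dusp9 as in XY ESC, had 0.527 (SD 0.347, 11 of 11 above 0), but 1 library cannot exclude it. Label and line cannot be separated here.

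The XX effect differed between E11.5 EGC and ESC by a direct test for 2164 genes. For Dusp9 the difference was 0.851 with E11.5 XY EGC as the reference, but -0.363 (adjusted p = 0.0649) with E12.5 XY EGC. For the list medians it was -0.463 in germline genes silenced by promoter methylation, -0.353 in ERK targets, -0.412 in p53 and stress genes and 0.293 in cholesterol synthesis. With E12.5 XY EGC as the reference these medians were -0.400, -0.330, -0.265 and 0.035, and of these lists only ERK targets were called (adjusted p = 0.0257, and adjusted p = 0.701 with an estimated correlation). The genes with the most negative differences were Fosb (-5.03), Fos (-3.95), Atf3 (-3.63), Egr1 (-3.25), Egr2 (-2.90), Dll1 (-2.73), Osr2 (-2.62), Ptgs2 (-2.29), Klf6 (-2.27) and Klf4 (-2.19). Those with the most positive ones were the pseudogene Eif4a-ps4 (2.18), the histone genes Hist1h4n (2.08), Hist1h2ao (1.64) and Hist1h4b (1.60), Dok2 (1.93), Ina (1.76), the keratin gene Krt42 (1.75), Insl3 (1.69), the tubulin gene Tubb3 (1.65) and the connexin gene Gjb1 (1.54). Without EGC 9 the calls of Eif4a-ps4 (adjusted p = 0.0827), Hist1h4n (0.0572) and Insl3 (0.0581) were lost. Hist1h2ao was lost without EGC 4 (0.0688), EGC 5 (0.0608), EGC 9 (0.1595), ESC 1 (0.0737), ESC 2 (0.0746) or ESC 6 (0.0855), and Hist1h4b without EGC 5 (0.0831), EGC 7 (0.0508), EGC 9 (0.142), ESC 1 (0.0614), ESC 2 (0.0781), ESC 5 (0.0535) or ESC 6 (0.0836). Hist1h2ao was also lost with a pseudocount of 5 (0.0592), without a filter (0.0852) and with robust variances (0.0561), and Hist1h4b with a pseudocount of 0.1 (0.0540) and without a filter (0.0822). The other 15 genes kept their calls in every fit with the E11.5 reference. With E12.5 XY EGC as the reference, only Fosb, Fos, Egr1, Klf6, Klf4, Hist1h4n and Krt42 of the 20 genes passed, and Ptgs2, Eif4a-ps4 and Hist1h2ao changed sign without passing, so most of these differences rest on the E11.5 XY EGC libraries.

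Further single libraries lay far from the rest of their group. EGC 8 scored -0.0484 on chromosome 2 and had 17.8 TPM of Rlim, an X-linked ubiquitin ligase gene. In EGC 4 the fibroblast marker mean was 3.58, Col1a1 had 12.8 TPM and Col1a2 12.9 TPM. Grb10 had 97.3 TPM in EGC 6. The chaperone gene Hspa5 had 380.0 TPM in ESC 6, and ESC 1 had 7725 TPM of mt-Co1 and 1016 TPM of mt-Nd5. In all 11 of 188 groups tested had such a library, and chance gives 9.4.

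Other splits of the same libraries were counted for comparisons with at least 3 libraries a side. For EGC against ESC, 3 of 100 splits gave as many genes as the real one, the real one included. These splits moved single libraries and so mostly broke up header labels, which the real one keeps whole. The share therefore cannot exclude chance. Libraries of a label are correlated (0.751) in a fit with only EGC and ESC as groups. This value therefore also takes up karyotype and stage differences between labels. With labels treated as correlated no gene passed in limma. There, 133 had an unadjusted p under 0.05, a smaller share of the 12909 genes than chance would give. The loss of calls cannot be put down to few independent lines per label alone, and these stay open. The real count was 6 and the highest other 4209, in a split with 5 of its 6 smaller-side libraries XX, which points to karyotype as a structure of the samples. For EGC against ESC in XY cells with a fit of 2 groups, 3 of 84 splits gave as many, the real one included with 8 genes. The others gave 4215, with the E11.5 XY EGC libraries on their own, and 599, with the E12.5 XY EGC libraries on their own. All 3 keep header labels whole, so this share cannot tell a difference between EGC and ESC from one between labels. In fits of only the 6 libraries compared, for XX against XY in ESC the real count was 5691 and the highest other 1, and for E12.5 against E11.5 XY EGC the real count was 4717 and the highest other 2. In each of these 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.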

How the results depend on the processing

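The alternatives to the comparisons by header label, the karyotype factor, correlated header labels, label means, left-out pairs or labels of libraries and left-out mitochondrial genes were chosen only after the data had been seen. The others were planned. The cause was not tested for the changes below, except where fewer genes, fewer libraries or a stricter bound follow from the alternative itself.

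For EGC against ESC, 6 genes were called with the settings used. The count was 2 without a filter, 13 with array weights, 11 with the X-to-autosome score and 3 with the fibroblast mean as a covariate, 2 at 2-fold or more, 21 with a karyotype factor and 3 without EGC 8 and ESC 3. It was 0 by the Wilcoxon test (smallest adjusted p 0.156, 1104 genes at an unadjusted p under 0.05), 0 by limma with correlated header labels (133 unadjusted) and 0 by limma on 1 mean per label (106 unadjusted). With 1 library left out it ranged from 2 to 21. The called lists were 6, or 2 with the fibroblast covariate, 1 with fry (fibroblast markers, FDR 0.00394) and 0 with an estimated correlation in camera (1 list at an unadjusted p under 0.05). Mest and Snrpn passed in every limma fit to single libraries except with correlated labels (adjusted p 0.855 and 0.0941), where the log2 fold changes were 0.89 and 0.82 and the SE larger. Cdkn1c was not called without a filter (0.0528) or with correlated labels (0.9998). Bgn (0.0653, 0.9997 and 0.143), Vps13d (0.0537, 0.9997 and 0.130) and Gm6158 (0.0900, 0.271 and 0.182) were not called without a filter, with the fibroblast covariate or without EGC 8 and ESC 3, nor with correlated labels (0.9998 each). Gm6158 was also not called with a pseudocount of 0.1 (0.155) or 0.5 (0.0837) or without the XO library (0.0625), and neither it nor Vps13d was without the E11.5 XY EGC libraries (0.151). The Dusp9 difference stayed negative and past no threshold under all alternatives, at -0.40 to -0.98.

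At 2-fold or more, the calls fell to 1011 for XX against XY in ESC, 1056 in E11.5 EGC, 296 for their difference, 50 for EGC against ESC in XY, 121 in XX and 280 for E12.5 against E11.5. Array weights raised the difference to 4152, EGC against ESC in XY to 3579 and in XX to 3526, and Dusp9 in XX then passed at -0.23 (adjusted p = 0.0445). With the fibroblast covariate the XY and XX counts were 294 and 81, and with only the libraries compared the XX count was 613. With an estimated correlation camera called 0 lists in all 6 comparisons by label, against 2, 2, 0, 2, 1 and 0 at an unadjusted p under 0.05. Called lists numbered 8 without a filter and 9 without EGC 8 and ESC 3 for XX against XY in ESC, 2 without EGC 8 and ESC 3 for the difference, and 5 with a pseudocount of 0.1 for EGC against ESC in XX. For E12.5 against E11.5 they were 7 without a filter, 1 each with at least 1 TPM in 6 libraries, at least 5 TPM in 2 libraries, quantile scaling, median-ratio scaling and the fibroblast covariate, and 0 without mitochondrial genes (camera, 9 lists at an unadjusted p under 0.05).

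With 1 library left out, the gene counts ranged from 5429 to 6573 for XX against XY in ESC, 4967 to 7222 in E11.5 EGC, 698 to 2967 for the difference, 252 to 1239 for EGC against ESC in XY, 353 to 2324 in XX and 3862 to 5668 for E12.5 against E11.5. Called lists ranged from 5 to 9, 3 to 4, 2 to 5, 5 to 8, 2 to 4 and 1 to 7 in the same order, and from 4 to 7 for EGC against ESC. Where leaving out EGC 7 or EGC 9 left 1 XX EGC library, that library is assumed to vary like the other groups. The X-to-autosome difference between XX and XY stayed between 0.874 and 0.903.

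Of the relations within XY libraries, those of the X score with germline and ERK genes turned to -0.351 and -0.003 without the 2 farthest libraries. Over all genes taken by the naming rule, signs changed in 123 of 2198 values for EGC against ESC (21 genes, none past the threshold on either side), 4 of 3186 for XX against XY in ESC, 11 of 3323 in E11.5 EGC, 38 of 3004 for the difference, 9 of 2824 for EGC against ESC in XY, 16 of 2930 in XX and 2 of 3009 for E12.5 against E11.5. In E11.5 EGC, 8 of the 11 were called on at least 1 side, all with E12.5 XY EGC as the reference, as were 14 of the 38 for the difference, among them Rhox6 (-1.54, adjusted p = 0.00536) and Lox (1.69, 0.000301), named after their values were seen. With E12.5 XY EGC as the reference for the difference, Dusp9 turned to -0.363, Ptgs2 to 0.331, Eif4a-ps4 to -0.291 and Hist1h2ao to -0.358, none of them past the threshold. No other gene with such changes is discussed in the text for the same comparison. No read depth is known, so nothing can be said of counting error.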

Other observations

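The tests of Mest and Snrpn given here were chosen only after the result was seen, except that the fit with the fibroblast marker mean as a covariate had been planned.

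The XO library can be set beside the other E11.5 EGC as values only. It had no more than 0.173 TPM of Eif2s3y, Ddx3y or Uty, and 33.6 TPM of Dusp9. It had 27.9 TPM of Fos and 5.27 TPM of Egr1, against 24.3 and 2.94 TPM in XX EGC and 626.5 and 142 TPM in E11.5 XY EGC. Dusp6 had 21.5 TPM, against 21.5 TPM in XY ESC and 43.3 TPM in E11.5 XY EGC. Meg3 had 665 TPM, against 665 ± 78.2 TPM in E11.5 XY EGC and 196 TPM in XX EGC, but it lies on chromosome 12, which was raised 1.33-fold as a whole in this library. Impact had 69.1 TPM, as in XY ESC (69.1 ± 8.31 TPM), and not the 177 ± 8.86 TPM of E11.5 XY EGC. Mest at 55.2 TPM and Snrpn at 166 TPM were the highest of all libraries.

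Some X-linked genes known from the male germline were nearly confined to the XX labels. Scml2 had 72.7 ± 24.1 TPM in the 5 XX libraries (SD), 3.02 ± 1.07 TPM in the 9 XY libraries and 1.69 TPM in the XO library. Usp26 had 32.1 ± 5.29, 1.73 ± 1.24 and 0.736 TPM, and Rhox1 39.6 ± 6.00, 1.48 ± 0.643 and 0.757 TPM. The autosomal germline gene Dazl had 70.1 ± 19.7 TPM in XX, 23.4 ± 5.05 TPM in XY and 13.8 TPM in XO libraries. The imprinted genes Zrsr1 and Phlda2 set XY ESC apart from all other labels. Zrsr1 had 5.499 ± 0.677 TPM in XY ESC and 10.4 to 12.2 TPM in EGC libraries of every karyotype, with 10.96 ± 0.861 TPM in XX ESC. Phlda2 had 81.6 ± 10.6 TPM in XY ESC and at most 32.4 TPM in any other library. Grb10 had 89.4 ± 4.51 TPM in XY ESC, 25.3 ± 0.508 TPM in the 5 XX libraries, 14.2 TPM in the XO library and 4.19 ± 0.163 TPM in E12.5 XY EGC. In E11.5 XY EGC it had 97.3 TPM in EGC 6 and 7.13 and 8.36 TPM in the other 2 libraries. These genes were chosen after their values were seen.

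Mest and Snrpn were higher in all 9 EGC libraries. RNA from feeder fibroblasts is argued against, because with the fibroblast marker mean as a covariate the smaller of both log2 fold changes was 0.855 ± 0.128 and both passed (adjusted p = 0.0312). An unequal share of XX libraries is argued against too, as the smaller was 0.807 ± 0.0734 with karyotype as a factor. Few independent lines per label stay open, since with libraries of a label treated as correlated the larger adjusted p in limma was 0.855. The correlation in that fit also takes up karyotype and stage differences between labels. There the folds did not shrink (Mest 0.849 ± 0.0838 before and 0.891 ± 0.190 after, Snrpn 0.794 ± 0.0866 and 0.817 ± 0.130), and the calls ended because the SE grew. A hypothesis is that EGC may have lost methylation imprints that silence the maternal copy. Of 15 other genes under maternally methylated regions, 7 were higher and none lower in XY EGC than in XY ESC by limma (10 at an unadjusted p under 0.05), with a median of 0.924 for those 7 and 0.358 for all 15, but none was called in XX EGC against XX ESC (1 at an unadjusted p under 0.05, median -0.0961), so this test does not decide.

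In XX ESC 11 of the same 15 genes were higher than in XY ESC and 1 was lower. Between XX and XY in E11.5 EGC, 7 were higher and 4 lower in XX, with a median of 0.0741 over the 15. Of 4 genes that such loss would lower, Cdkn1c, Phlda2 and Slc22a18 were lower in XY EGC, and Cdkn1c, Slc22a18 and Igf2r in XX EGC. In XX against XY ESC, 1 of these 4 was higher and 2 were lower. All these counts are of genes, and genes that share a region are not independent. The other measured genes of the Snrpn region did not rise as Snrpn did. Ndn, Mkrn3 and Peg12 had a median of 0.145 (SD 0.268) in XY EGC against XY ESC, where Snrpn rose by 0.97. Limma called none of the 3 (1 at an unadjusted p under 0.05). In XX against XY ESC, Ndn, Peg12 and Mkrn3 rose by 1.62, 1.70 and 0.30, where Snrpn rose by 0.43. Since genes of this region can move apart from Snrpn, they do not decide on loss over the whole region. Methylation was not measured in these libraries, so the hypothesis was tested through expression alone.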
